A study of Arabidopsis thaliana with 51 samples.

How the data were processed

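RNA of whole seedlings was hybridised to 51 Affymetrix ATH1 arrays by the authors, 3 biological replicates in each of 17 groups. Per the labels, seedlings grew 5 to 6 days on agar and 5 to 6 days in liquid medium under 12 h of light and 12 h of dark, and were treated with 1 µM peptide. The deposited values are log2 probe-set expression made by the authors with GCRMA, a background correction and quantile normalisation for Affymetrix arrays. The labels name GCRMA and give no version, filter or other step. All arrays share the same lowest value, 2.08, and 27.4% of all values lie within 0.1 of it. No detection calls are used here, so a difference against a group near that value is on the scale of the background correction. Arrays have no depth, and their number limits the precision.

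The table holds 22810 probe sets, of which 64 are control probe sets. The annotation table pairs 13513 of the others with exactly 1 gene, 503 with several and 8730 with none, and a probe set was named only where it is paired with 1 gene. No genome build is given for the probe sets, so no positions are printed. Probe sets were tested if they reached a log2 value of 5 on at least 3 arrays, which left 14568, of which 7828 have 1 gene.

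Each probe set was fitted with limma 3.58.1 in R 4.3.3 with a mean per group over all 51 arrays, and contrasts were tested with moderated statistics (34 residual and 3.84 prior degrees of freedom). The p values were adjusted by Benjamini-Hochberg within each contrast. A probe set was called at an adjusted p under 0.05 with at least a 2-fold difference. The 26 contrasts were the 12 responses of a line against its own 0 h group, the 4 baseline differences from WT, the 8 interactions and the 2 differences between peptides in WT at matched times. Interactions subtract the WT response from that of the mutant. For the slope on the WT response, each treated mutant array minus the untreated mutant mean was regressed through 0 on the WT changes over the probe sets called in WT. The overlap of 2 responses is given beside the count for independent lists and, where arrays are shared, beside 20 simulated sets of unchanged groups.

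Gene lists were tested with camera, with a preset correlation of 0.01 between genes, against the other genes, and adjusted over 754 tests of 29 lists in 26 contrasts. Beside it stand camera with an estimated correlation and fry. Of 20 lists fixed beforehand with 386 genes, only 48 genes have a name on the array table and 44 were measured, so 5 lists with at least 3 measured members were tested. Another 24 lists were written from the symbols of the annotation table before any expression value was examined, and the immune signalling list shares genes with the immunity marker list, the receptor list, the U-box list and the glycosyltransferase list. The berberine bridge enzyme-like list holds the cluster around AT1G26380 and members of the family elsewhere in the genome. It shares AT1G26380 with the immunity marker list. With the preset correlation 181 tests passed, and 23 of them also with an estimated correlation. A list of low-oxygen response genes was written after the values were seen. Names come from the annotation table, and the short descriptions of gene products are general knowledge of these genes and not taken from it.

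The named genes follow a rule set before the data were examined. With 1 probe set per gene, the text may name EFR, EIN2, BAK1, PEPR1 and PEPR2, the 6 genes with the largest increase and the 6 with the largest decrease in each contrast, and up to 4 members of each list with the largest change. The groups, the contrasts and the alternatives were also set before the data were examined. The alternatives were no low-value filter, a filter at log2 7, an intensity trend, a fit of only the groups compared, the replicate number as a block, quantile normalisation, median centring, no fold minimum, array weights, and leaving out each array. A fit without the array with the widest residuals, and the immune signalling list without EFR in the efr contrasts, were added after the values were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

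The procedure was tested on simulated data of 14568 probe sets. For the WT response at 10 h of elf18 it recovered 95% of 100 probe sets changed by 1.5 on the log2 scale and 100% of those changed by 3. For the efr interaction it recovered 90% and 100%. A simulated slope of 0.5 was estimated as 0.493. Replicate numbers were examined for pairing through the residuals of the fit. Pairs with the same number correlated at 0.078 on average and pairs with different numbers at -0.039, and on the first component (13.7%) all 17 arrays numbered 3 lay above 0 and 15 of those numbered 2 below it. Arrays thus share some structure by number, which the labels do not explain. Every same-numbered pair passed 0.1 only in 2 contrasts, the ein2 response at 2 h of Pep2 (0.18 to 0.24) and the ein2 baseline (0.13 to 0.29). There the pairing comes from the data alone. The numbers entered as a block in an alternative.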

Results

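The series measured transcript levels in whole Arabidopsis thaliana seedlings with Affymetrix ATH1 arrays after treatment with 1 µM of an elicitor peptide. The peptide elf18 comes from bacterial elongation factor Tu and is perceived by the receptor kinase EFR, whereas Pep2 is a plant peptide perceived by the receptor kinases PEPR1 and PEPR2. Besides wild type (WT), the lines were ein2-1, which lacks a protein needed for ethylene signalling, bak1-3, which lacks a co-receptor kinase, and the receptor mutants efr-1 and pepr1-1 pepr2-3. The 51 arrays form 17 groups of 3. WT was sampled untreated (0 h) and at 2 h and 10 h of each peptide, ein2 at 0 h, at 2 h and 10 h of elf18 and at 2 h of Pep2, efr at 0 h and at 10 h of elf18, and both pepr1 pepr2 and bak1 at 0 h and at 2 h and 10 h of Pep2. Array medians lay between 6.04 and 6.15 on the log2 scale, and arrays of a group correlated at 0.977 or more. The number of arrays limits the precision of every value below.

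The series holds no untreated seedlings at 2 h or 10 h, so each response against 0 h contains elapsed time as well as the peptide. The receptor mutants given the same peptide for the same time are the background where they were sampled. At 2 h of elf18 efr was not sampled, so the responses there have no such background. A genotype is compared with WT through the difference between their responses (the interaction). Changes are log2 differences, written with their SE from limma, and levels are the mean ± SD of 3 arrays. A transcript counts as changed at an adjusted p under 0.05 with at least a 2-fold difference. Many transcripts sit at the lowest value of the table, 2.08, and the size of a change from or to that value depends on the authors' background correction.

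The EFR transcript itself marked the efr line. It stood at 3.22 ± 0.32 (SD, n = 3) in untreated WT and at 2.2 ± 0.07 in untreated efr, close to the lowest value, and stayed at 2.17 ± 0.01 in efr after 10 h of elf18. In WT it rose with both peptides, to 6.37 ± 0.26 after 2 h and 6.94 ± 0.19 after 10 h of elf18, and to 6.69 ± 0.22 and 5.53 ± 0.20 at the same times of Pep2. The names paired with the probe sets do not include EIN2, BAK1, PEPR1 or PEPR2, so their levels are not given here.

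The first comparison asks which transcripts respond to elf18 in WT. After 2 h, many defence transcripts had risen from low levels. AT1G26380, which encodes a berberine bridge enzyme-like oxidase, rose by 7.24 (SE 0.567) to 10.79 ± 0.34, AT2G22880, which encodes a VQ-motif protein, rose by 6.73, and AT3G47380, which encodes an invertase/pectin methylesterase inhibitor family protein, rose by 7.25. The transcription factor gene WRKY22 rose by 5.19, the U-box ubiquitin ligase genes PUB22 and PUB23 by 4.50 and 2.92, and the receptor kinase genes AT1G51820 and SD1-29 by 5.03 and 3.65. The expansin-like gene EXLA1 fell by 3.48, and AT1G48100, which encodes a polygalacturonase-like protein, fell by 4.29. Of 14568 probe sets tested, 1189 were higher and 923 lower than at 0 h.

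Gene lists were also tested at 2 h of elf18. All 6 measured pattern-triggered immunity markers rose, also 6 when adjusted over the list alone, with a median of 3.71 (camera adjusted p = 3.8e-07, adjusted p = 0.026 with an estimated correlation). So did 10 of 12 immune signalling genes (median 2.62, adjusted p = 4.6e-09, and 0.022 as the adjusted p with an estimated correlation). From the berberine bridge enzyme-like list 5 of 6 genes rose and from the receptor kinase cluster on chromosome 1 6 of 7, with adjusted p values of 1e-05 and 4.2e-06. With an estimated correlation their adjusted p values were 0.053 and 0.078. Of 15 endoplasmic reticulum folding genes 6 rose (adjusted p = 2.7e-05, adjusted p = 0.08 with an estimated correlation).

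By 10 h of elf18 the response was wider, with 1952 probe sets higher and 1969 lower. PRX52, a peroxidase gene, went from 2.08 ± 0.00 to 11.49 ± 0.60, and AT5G39580, a second peroxidase gene, rose by 7.97 (SE 0.319) to 13.84 ± 0.15. AT4G12500, which encodes a lipid transfer protein-like protein, reached 15.20 ± 0.04 after a rise of 8.42, and AT3G18250 and AT3G47480 rose by 8.51 and 7.51. Among decreases, AT3G21670, which encodes a nitrate transporter family protein, fell by 8.20 (SE 0.473) from 11.71 ± 0.05, and AT5G48490, which encodes another lipid transfer protein-like protein, fell by 7.47. The light-harvesting gene LHCB4.2 fell by 4.56 from 14.14 ± 0.09, CaS, which encodes a thylakoid calcium sensor, by 3.83, and NdhL, which encodes a subunit of the chloroplast NADH dehydrogenase-like complex, by 2.85. DFR of the anthocyanin pathway fell by 3.95, and UF3GT of the same pathway fell by 3.79.

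All 12 immune signalling genes rose at 10 h of elf18 with a median of 3.57 (adjusted p = 5.5e-08, adjusted p = 0.031 with an estimated correlation). The 6 pattern-triggered immunity markers rose too, WRKY53 by 4.14 and PUB22 by 4.07, 6 also when adjusted over the list alone (adjusted p = 0.00016, and 0.089 as the adjusted p with an estimated correlation). Of 29 nuclear photosynthesis genes 15 fell and 1 rose (median -1.03, adjusted p = 3.6e-06, adjusted p = 0.39 with an estimated correlation), and all 5 flavonoid and anthocyanin genes fell, 5 also when adjusted over the list alone (median -1.92, adjusted p = 0.024, adjusted p = 0.48 with an estimated correlation). From the xyloglucan endotransglucosylases, which remodel the cell wall, 5 of 9 fell (adjusted p = 0.0097, adjusted p = 0.19 with an estimated correlation), while 11 of 35 UDP-glycosyltransferases rose and 4 fell (adjusted p = 0.21), UGT76B1 by 3.31.

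**Figure D1:**
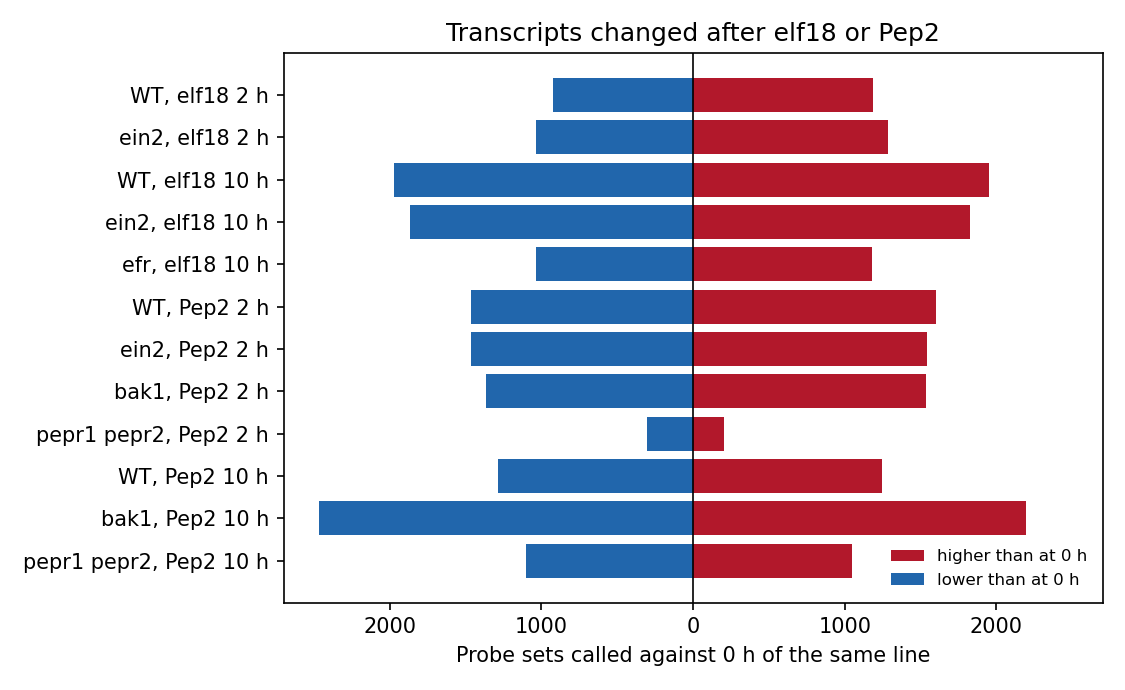
Number of probe sets called higher (red, to the right) or lower (blue, to the left) than at 0 h of the same line, for each treated group of 3 arrays. Both directions count from 0 at the centre line, and pepr1 pepr2 at 2 h of Pep2 has the shortest bars, with 207 higher and 307 lower.

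The efr line shows which part of the elf18 response at 10 h needs the receptor. PRX52 stayed at 2.1 ± 0.01 in treated efr, AT3G18250 at 3.08 ± 0.52 and AT1G26380 at 2.25 ± 0.00. AT5G39580 reached 6.59 ± 0.97 against 13.84 ± 0.15 in WT, an interaction of -7.15 (SE 0.451, adjusted p = 6.6e-16). In the other direction DFR stood at 7.75 ± 0.46 in treated efr against 2.44 ± 0.27 in treated WT, and NdhL at 10.38 ± 0.10 against 6.73 ± 0.27. AT2G10940, which encodes a lipid transfer protein family member, stood at 12.02 ± 0.14 against 6.04 ± 0.45.

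The immune signalling list holds EFR itself, the gene mutated in this line, and was taken here without it. All 11 other immune signalling genes had a lower response in efr than in WT (median -3.03, adjusted p = 2.3e-07, adjusted p = 0.032 with an estimated correlation). So had all 6 immunity markers, 6 also when adjusted over the list alone (adjusted p = 5.4e-05, adjusted p = 0.077 with an estimated correlation). Of the 29 nuclear photosynthesis genes 17 had a higher response in efr and none a lower one (adjusted p = 4.6e-09, adjusted p = 0.26 with an estimated correlation). In all, 2136 probe sets responded higher and 1842 lower in efr than in WT. Over the probe sets called in WT, the efr response had a slope of 0.290 ± 0.037 (SD, n = 3 arrays) on the WT response, where 1 would be the whole of it. The slope was 0.165 over transcripts that rose in WT and 0.480 over those that fell.

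Pep2 also raised defence transcripts in WT at 2 h, some of them raised by elf18 as well. AT1G26380 rose by 7.37 (SE 0.567) to 10.92 ± 0.31 and AT2G22880 by 7.04, while BGLU27, a beta-glucosidase family gene, went from 2.08 ± 0.00 to 9.99 ± 0.32. WRKY53 and WRKY6, transcription factor genes, rose by 5.13 and 4.2, PUB24 by 4.98, and CCR2, which encodes a cinnamoyl-CoA reductase, by 6.05. AT4G18250, a receptor kinase family gene, rose by 6.83 (SE 0.198), the auxin-conjugating enzyme gene GH3.3 by 4.37 and the cytochrome P450 gene CYP71B22 by 4.12. TBL36 fell by 3.65, the xyloglucan endotransglucosylase gene XTH21 by 2.91, the expansin gene EXPA15 by 1.84 and AUR2, which encodes an Aurora kinase of mitosis, by 2.06. The counts were 1605 higher and 1462 lower.

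At 2 h of Pep2 all 12 immune signalling genes rose (median 2.79, adjusted p = 1.8e-09, adjusted p = 0.022 with an estimated correlation). All 6 immunity markers rose as well, 6 also when adjusted over the list alone (median 3.96, adjusted p = 5.5e-06, adjusted p = 0.041 with an estimated correlation). From the U-box ubiquitin ligases 4 of 7 rose (adjusted p = 0.0017, adjusted p = 0.035 with an estimated correlation). Of 11 expansins 6 fell and 2 rose, and of 9 xyloglucan endotransglucosylases 6 fell and 2 rose, with adjusted p values of 0.29 and 0.18.

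After 10 h of Pep2, 1248 probe sets were higher and 1289 lower. PRX52 reached 11.12 ± 0.32, and 2 other peroxidase genes, AT5G06730 and AT4G08780, rose by 6.68 and 6.53. The cupredoxin gene AT2G15780 and AT5G52390 went from 2.08 ± 0.00 to 9.51 ± 0.19 and 9.34 ± 0.22. The defensin genes PDF1.2, PDF1.2b and PDF2.1 rose by 2.94 (SE 0.765), 3.6 and 4.27 and the calmodulin-like gene CML41 by 5.16. Of the 10 measured defence peptides and PR proteins 4 rose and 1 fell (adjusted p = 0.15). WRKY53 was still 2.37 and AT1G26380 2.67 above 0 h. BCAT4, an enzyme gene of aliphatic glucosinolate synthesis, fell by 2.49, the glutathione transferase gene GSTU20 fell by 2.22 and AT5G48490 fell by 6.11. Of the immune signalling genes 8 of 12 rose (adjusted p = 0.00036, adjusted p = 0.15 with an estimated correlation) and of 12 glutathione transferases 6 fell (adjusted p = 0.0036, adjusted p = 0.16 with an estimated correlation).

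Without PEPR1 and PEPR2 the early response to Pep2 was nearly absent. At 2 h AT1G26380 stood at 2.35 ± 0.18 in the treated mutant against 10.92 ± 0.31 in WT, BGLU27 at 2.08 ± 0.00, AT2G22880 at 3.00 ± 0.26 and WRKY53 at 5.58 ± 0.47 against 11.37 ± 0.11. AUR2 was 6.56 ± 0.41 in the treated mutant against 4.37 ± 0.71 in WT. All 12 immune signalling genes and all 6 immunity markers, 6 also when adjusted over the list alone, responded lower than in WT (adjusted p = 1.1e-09 and 4.2e-06, adjusted p = 0.022 and 0.041 with an estimated correlation). The slope on the WT response was 0.042 ± 0.019 (SD, n = 3 arrays), -0.02 over transcripts that rose in WT and 0.188 over those that fell. It was 0.026, 0.074 and 0.027 without pepr1 pepr2 untreated replicates 1, 2 and 3. Responses were higher in the mutant for 1649 probe sets and lower for 1720.

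By 10 h the pepr1 pepr2 line had changed far more, with 1051 probe sets higher and 1103 lower than at 0 h, and its slope on the WT response was 0.657 ± 0.043. PRX52 nevertheless stayed at 2.13 ± 0.09, and AT2G15780 and AT5G52390 at 2.08 ± 0.00. PDF1.2b stood at 10.15 ± 0.83 in the treated mutant against 13.36 ± 0.07 in WT (interaction -4.06, adjusted p = 0.00036). AT5G07030, which encodes an aspartyl protease family protein, was 8.64 ± 0.37 against 4.63 ± 0.61. The interaction comprised 558 probe sets higher and 697 lower, with 4 of 12 immune signalling genes lower (adjusted p = 0.0017, adjusted p = 0.21 with an estimated correlation).

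**Figure D2:**
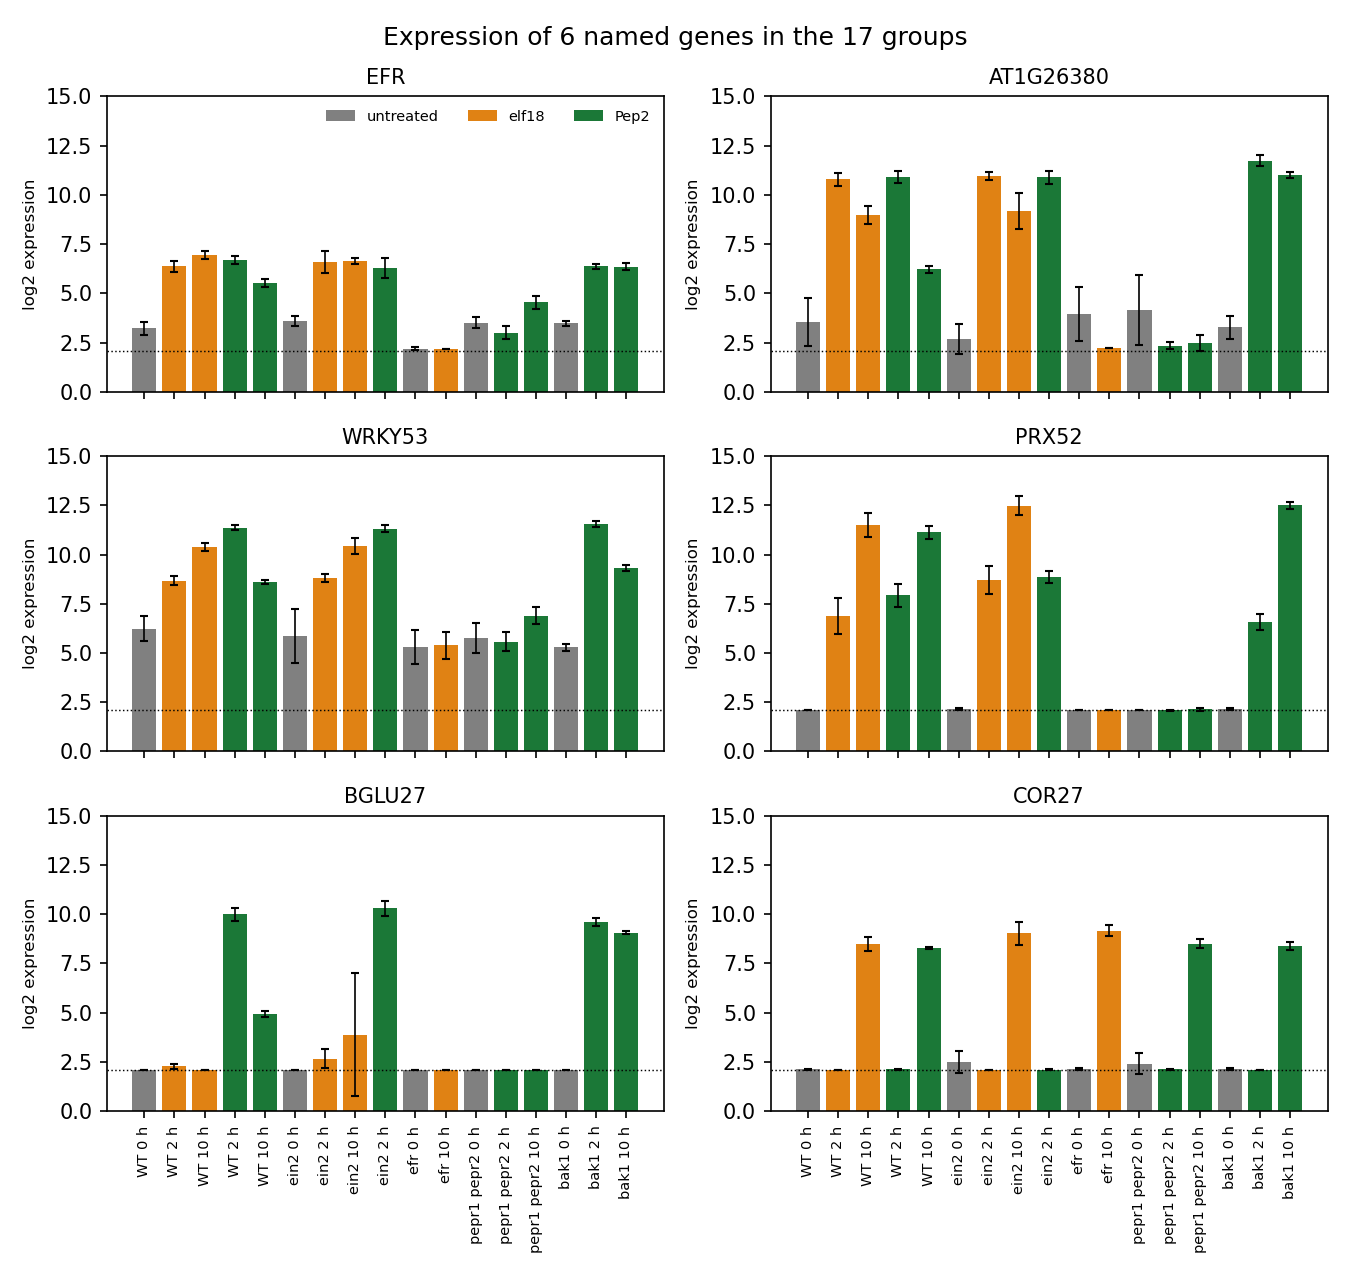
Expression (log2, bars give the mean and error bars the SD of 3 arrays) of 6 genes in the 17 groups, with untreated groups in grey, elf18 in orange, Pep2 in green and the lowest value of the table as a dotted line. EFR is near that line in both efr groups, AT1G26380, WRKY53 and PRX52 rose with both peptides in WT, BGLU27 reached 9.99 with Pep2 at 2 h in WT, and COR27 rose at 10 h in every line sampled then.

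Many transcripts changed at 10 h in both receptor mutants. COR27, a cold- and clock-regulated gene, rose by 7.01 (SE 0.213) in efr and by 6.07 in pepr1 pepr2, and by 6.18 in WT with Pep2. AT1G07050, which encodes a CCT-motif protein, rose by 7.29 and 6.69, AT1G56300, which encodes a DnaJ-domain protein, by 6.84 and 5.89, and AT3G62550, a universal stress protein family gene, by 5.98 and 4.94. AT3G29970 fell by 7.76 in efr and fell by 9.03 in pepr1 pepr2. In both mutants 749 probe sets were higher (85 for independent lists) and 787 lower (78.5), and none moved in opposite directions. The 2 responses share no array and correlated at 0.881 across probe sets, which are not independent replicates.

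Matched times allow the peptides to be set against each other in WT. At 2 h BGLU27 stood at 2.27 ± 0.12 with elf18 and at 9.99 ± 0.32 with Pep2, AT3G48450, which encodes a NOI-domain protein, at 4.52 ± 0.61 and 10.54 ± 0.13, and CYP71B22 at 2.63 ± 0.31 and 6.60 ± 0.93. WRKY53 was lower with elf18 by a difference of -2.68 (SE 0.418), whereas WRKY22 was higher by 2.56 and AT5G48430, an aspartyl protease family gene, by 3.40. At 10 h the nitrate transporter gene NRT2.5 stood at 8.42 ± 0.57 with elf18 and 2.09 ± 0.02 with Pep2, AT1G26410 of the berberine bridge enzyme-like cluster at 9.38 ± 0.18 and 3.15 ± 0.61, and the glutamate receptor-like gene ATGLR1.2 at 7.66 ± 0.50 and 2.13 ± 0.06. Higher with Pep2 were PDF1.2, at 10.79 ± 0.06 against 6.41 ± 0.56, AT2G15780, at 9.51 ± 0.19 against 2.08 ± 0.00, NdhL, at 9.25 ± 0.20 against 6.73 ± 0.27, and DFR, at 6.19 ± 0.43 against 2.44 ± 0.27.

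At 10 h 10 of 12 immune signalling genes were higher with elf18 than with Pep2 (median 1.78, adjusted p = 2.5e-07, adjusted p = 0.038 with an estimated correlation), PUB22 by 3.87 and WRKY22 by 3.2. At 2 h 2 of the 12 were higher and 4 lower (adjusted p = 0.043, adjusted p = 0.46 with an estimated correlation). Of the nuclear photosynthesis genes 10 of 29 were lower with elf18 at 10 h (adjusted p = 2.9e-08, adjusted p = 0.29 with an estimated correlation). The differing probe sets numbered 555 higher and 597 lower with elf18 at 2 h, and 1162 and 1032 at 10 h. Transcripts raised at 2 h of elf18 had a median change of 1.73 then and 2.13 at 10 h, whereas those raised at 2 h of Pep2 went from 1.89 to 0.78. For transcripts lowered at 2 h the medians went from -1.35 to -1.73 with elf18 and from -1.45 to -0.82 with Pep2.

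The responses to both peptides overlapped in WT. At 2 h 996 probe sets rose with both (131 for independent lists), 664 fell with both (92.6) and 3 went opposite ways. At 10 h these were 910 (167.2), 952 (174.2) and 33. Both responses use the same 3 arrays at 0 h, which cannot be split, so part of the excess may come from them. Elapsed time is also part of both responses. At 10 h efr and pepr1 pepr2, each without the receptor of its peptide, shared 749 higher and 787 lower probe sets. How many of these are also in the overlap in WT at 10 h was not counted. The part of that overlap that does not come from the peptides is thus not known. Simulated unchanged groups with a shared control had at most 1 probe set called, so their 0 called alike in both responses cannot measure that part. Across probe sets their changes correlated at 0.502 with a covariance of 0.02. In the data these were 0.827 and 0.841 at 2 h, and 0.749 and 0.972 at 10 h. The simulation held no effect of elapsed time.

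Ethylene-insensitive ein2 seedlings differed from WT before treatment. The anthocyanin pathway genes DFR and UF3GT were higher in ein2 by 3.18 (SE 0.651) and 3.27, and AT4G14090, an anthocyanin glucosyltransferase gene, by 3.93. AT1G66100, a thionin gene, stood at 7.38 ± 0.76 in ein2 and 2.28 ± 0.11 in WT. AT4G33720, which encodes a PR1-like secreted protein, stood at 2.13 ± 0.06 in ein2 against 10.50 ± 2.55 in WT, the peroxidase gene AT5G19890 at 2.31 ± 0.02 against 9.03 ± 0.95, and the organ growth gene ARL at 5.37 ± 0.46 against 11.43 ± 0.25. RTE1, an ethylene signalling gene, was lower by a difference of -1.12. In all 333 probe sets were higher and 327 lower, and 3 of 5 flavonoid and anthocyanin genes were higher, 3 also when adjusted over the list alone (adjusted p = 1.7e-06, adjusted p = 0.094 with an estimated correlation).

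With these differences present, most of the response to either peptide was present in ein2. AT1G26380 reached 10.95 ± 0.20 at 2 h of elf18 and 10.90 ± 0.32 at 2 h of Pep2, BGLU27 reached 10.30 ± 0.39 with Pep2, and PRX52 reached 12.47 ± 0.48 at 10 h of elf18. All 12 immune signalling genes rose in ein2 at 10 h of elf18, and none of the 12 passed as differing from WT at that time or at 2 h of either peptide (medians of the difference 0.14, 0.28 and -0.09). The slopes on the WT response were 1.001 ± 0.021 at 2 h and 0.894 ± 0.063 at 10 h of elf18, and 0.951 ± 0.034 at 2 h of Pep2 (SD, n = 3 arrays each).

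Single transcripts stood lower in treated ein2 than in treated WT. NRT2.5 stayed at 2.09 ± 0.00 in ein2 at 2 h of elf18 against 5.57 ± 0.57 in WT, and at 2.99 ± 1.17 against 8.42 ± 0.57 at 10 h (interactions -3.48 and -5.42). AT4G28420, an aminotransferase family gene, stayed at 2.27 ± 0.10 at 10 h against 7.05 ± 0.24, and CYP71B22 at 2.66 ± 0.36 at 2 h of Pep2 against 6.60 ± 0.93. In the other direction LHCB4.2 stood at 11.43 ± 0.68 in ein2 at 10 h against 9.58 ± 0.52. UF3GT fell by 6.03 in ein2, from 9.24 ± 0.35 to 3.21 ± 0.41, to near its level in treated WT.

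Responses of ein2 differed from WT in 101 probe sets higher and 99 lower at 2 h of elf18, 369 and 290 at 10 h of elf18, and 198 and 184 at 2 h of Pep2. The total of 200 at 2 h of elf18 became 127 with only the groups compared in the fit, and the Pep2 total of 382 became 204 without ein2 untreated replicate 1. In replicate 1 of ein2 at 10 h of elf18, AT4G33720 stood at 9.57 and BGLU27 at 7.49. In the other 2 replicates BGLU27 stayed at the lowest value of the table, and without this array the slope at 10 h was 0.928 and the differing probe sets numbered 652.

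**Figure D3:**
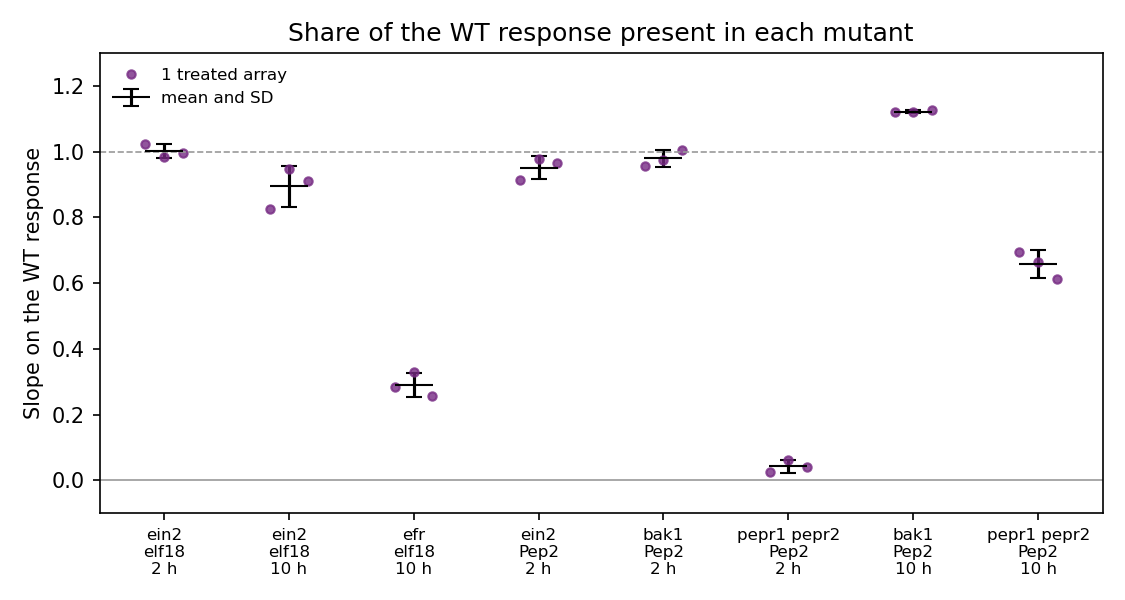
Slope through 0 of each mutant's log2 changes on those of WT, over the probe sets called in the WT response, with 1 point per treated array and the mean and SD of 3 arrays. A slope of 1 (dashed line) is the whole WT response, and pepr1 pepr2 at 2 h of Pep2 lies at 0.042 and bak1 at 10 h of Pep2 at 1.122.

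The Pep2 response was also measured in bak1, the only co-receptor mutant among the lines. At 2 h bak1 responded much as WT did: AT1G26380 rose by 8.47 (SE 0.567), STZ, a zinc-finger transcription factor gene, by 8.07 and WRKY53 by 6.27. The slope on the WT response was 0.979 ± 0.024 (SD, n = 3 arrays). CML37, a calmodulin-like gene, reached 7.23 ± 0.16 in bak1 against 2.18 ± 0.08 in WT, and AT4G27280, a calcium-binding protein gene, 12.82 ± 0.19 against 10.31 ± 0.24. In all 69 probe sets responded higher and 25 lower, a total of 94 that ranged from 45 (without WT Pep2 2h replicate 2) to 122 when 1 array was left out. The totals were 55 and 61 without WT Pep2 2h replicate 1 and without either of WT untreated replicates 1 and 2, and 56 without bak1 Pep2 2h replicate 2, and with array weights the total was 185.

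At 10 h the bak1 response to Pep2 was larger than that of WT. AT1G26390 of the berberine bridge enzyme-like cluster stood at 10.50 ± 0.33 in bak1 against 2.68 ± 0.00 in WT, AT1G26380 at 11.01 ± 0.13 against 6.22 ± 0.18, the beta-glucosidase gene BGLU45 at 8.22 ± 0.20 against 3.54 ± 0.19, and the glutaredoxin gene GRX480 at 7.58 ± 0.11 against 4.76 ± 0.82. AT4G03450, which encodes an ankyrin-repeat protein, and the glutathione transferase family gene AT5G44990 reached 7.68 ± 0.31 and 7.61 ± 0.17 against 2.08 ± 0.00 and 2.09 ± 0.01. PUB24 responded more by 2.53. Lower in bak1 were other transcripts: the lipase family gene AT5G45670 stood at 2.54 ± 0.40 against 7.93 ± 0.17, AUR2 at 2.46 ± 0.20 against 6.62 ± 0.27, the cell wall genes XTH32 at 6.33 ± 0.33 against 8.93 ± 0.27 and EXPB3 at 2.93 ± 0.38 against 5.79 ± 0.29, and BCAT4 at 5.75 ± 0.15 against 7.92 ± 0.47.

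All 6 measured genes of the berberine bridge enzyme-like list responded more in bak1 at 10 h (median 3.65, adjusted p = 3.1e-06, adjusted p = 0.041 with an estimated correlation). So did 6 of 12 immune signalling genes (adjusted p = 0.00095, adjusted p = 0.18 with an estimated correlation) and 4 of 6 immunity markers, 5 when adjusted over the list alone (adjusted p = 0.005, adjusted p = 0.22 with an estimated correlation). Of 14 cell division genes 5 and of 9 xyloglucan endotransglucosylases 6 responded lower, with 1 of the latter higher (adjusted p = 0.0013 and 0.028, adjusted p = 0.33 and 0.29 with an estimated correlation). The response comprised 2196 probe sets higher and 2467 lower than at 0 h, and its difference from WT 973 and 1218. Its slope on the WT response was 1.122 ± 0.005, or 1.321 over the 724 probe sets whose response differed between pepr1 pepr2 and WT. Of these, 688 responded less and 36 more in pepr1 pepr2.

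The efr, pepr1 pepr2 and bak1 lines were close to WT before treatment, with 12, 12 and 10 probe sets called. With only the groups compared in the fit these counts were 0, 2 and 0, none of the genes named next was called, and 1 regrouping of the arrays gave 13 for efr. With array weights the efr and bak1 counts were 48 and 29. In the fit of all groups, AT4G26460 was lower in efr by a difference of -2.62 (SE 0.354). AT5G66985 was higher in pepr1 pepr2 and in bak1 by 2.06 and 2.25, and its differences in ein2 and efr, 0.94 and 0.81, were not called. It belongs to the low-oxygen list, written after the values were seen. Of the 20 measured members of that list, 5 were higher and 0 lower in pepr1 pepr2, and 3 and 0 in bak1. In ein2 6 were higher and 2 lower, and in efr 1 and 1. Whether these differences come from the lines or from the state of the 0 h samples was not tested. All lines are compared with the same 3 WT arrays. The efr count lay between 1 (without WT untreated replicate 2) and 57 (without WT untreated replicate 3), and was 7 without WT untreated replicate 1 or efr untreated replicate 1 and 6 without efr untreated replicate 2. The pepr1 pepr2 count was 19 without WT untreated replicate 1.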

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

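The tests of time of day, of a difference at 0 h, of a longer lasting early response, of elapsed time and of remaining perception, the list without EFR, the directions set against scaling, and the count of splits that mix treated arrays, were chosen only after the results were seen, and the other tests here were set beforehand. The 8 interactions test whether a mutant's response differs from that of WT, and each called probe sets. The arrays of each interaction were also regrouped in 100 drawn splits, the real one included, in which mutant and WT arrays change places within the untreated and within the treated arrays.

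For pepr1 pepr2 at 2 h of Pep2, 4 of 100 splits gave as many as the 3369 probe sets called, with 3495 in the highest other. For pepr1 pepr2 at 10 h, 4 of 100 gave as many as 1255, with 1472 in the highest other. For bak1 at 2 h of Pep2, 1 of 100 gave as many as 94, with 68 in the highest other, which argues against chance but does not exclude it. That count was 63 with no low-value filter, 185 with array weights and 45 to 122 with 1 array left out. No split counts are given for those settings. For efr at 10 h of elf18, 9 of 100 gave as many as 3978, with 4409 in the highest other. The shares for pepr1 pepr2 at both times, for efr and for bak1 at 10 h turn on the splits that keep the treated arrays in their lines, which nearly copy the real contrast, so they do not decide whether chance is excluded. For ein2, 18 of 100 splits gave as many as 200 at 2 h of elf18 (highest other 1140). At 10 h of elf18 9 gave as many as 659 (1106), and at 2 h of Pep2 14 gave as many as 382 (981). Among the other splits that large, 11, 6 and 6 kept the treated arrays in their lines. However, ein2 differed from WT before treatment in 660 probe sets, and exchanging arrays puts that difference into the interaction. A split can thus pass the real count severalfold, as at 2 h of elf18. The ein2 shares therefore leave chance neither excluded nor supported. In the 88 splits that mix the treated arrays of the lines, the highest count was 3 for efr, 5 and 12 for pepr1 pepr2 at 2 h and 10 h, 19 and 9 for bak1 at 2 h and 10 h, and 1033, 855 and 805 for ein2 at 2 h and 10 h of elf18 and at 2 h of Pep2. For efr, for pepr1 pepr2 at both times and for bak1 at 10 h, these lie far below the real counts. But 3 treated arrays against 3 have only 10 splits, and the 88 repeat the mixed ones with different untreated arrays. That is too few for a share under 0.05, so whether chance is excluded is not decided here either.

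The larger response of bak1 at 10 h of Pep2 comprised 2191 probe sets, and 11 of 100 splits gave as many, with 2651 in the highest other, a share that decides nothing for the reason given above. The tables argue against a single array (at least 2045 probe sets with any of the 12 arrays left out) and against a difference already present at 0 h (median 0.01). Of the probe sets, 973 responded higher (median 1.54) and 1218 lower (median -1.40). These directions cannot test a shift common to all probe sets of an array, since the deposited values were already quantile normalised. Quantile normalization (2163) repeats that step and adds little. Another time of day at harvest stays open, since over probe sets changed alike in both receptor mutants the median interaction was -0.41, between the bounds set. A longer lasting early response may explain part of it, since 93.1% of the 1052 interaction probe sets called in WT at 2 h show the early sign. In bak1 those raised early went from 2.81 to 2.64 and those lowered early from -1.49 to -2.41. These medians decide nothing, since the probe sets were chosen for differing between bak1 and WT at 10 h. Over all 1605 probe sets raised in WT at 2 h, the medians went from 1.88 to 1.58 in bak1 and from 1.89 to 0.78 in WT. Over all 1462 lowered, they went from -1.37 to -1.52 in bak1 and from -1.45 to -0.82 in WT. But 1139 interaction probe sets were not called in WT at 2 h. This hypothesis, found and tested on the same data, thus leaves most of the pattern open.

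Both receptor mutants changed at 10 h of their peptide, with 2215 probe sets called in efr and 2154 in pepr1 pepr2. In both, 749 rose and 787 fell, but this cannot test a shift common to all probe sets, since the deposited values were already quantile normalised. Quantile normalization repeats that step, left the correlation at 0.881 and adds little. Remaining perception of elf18 in efr is argued against by a median of 0.07 over the immune signalling list, or 0.08 without EFR, while for Pep2 in pepr1 pepr2 the median of 0.5 leaves it open. Elapsed time, which includes the time of day, may account for the shared part, since the 2 responses share no array and correlated at 0.881. The series holds no untreated seedlings at 10 h, so a part due to handling cannot be separated from it.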

How the results depend on the processing

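A fit without ein2 elf18 10h replicate 1 for contrasts that do not hold it, and the immune signalling list without EFR, were chosen only after the values were seen, and the other alternatives were set before the data were examined. Counts on the full set of arrays stand in the report.

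With no fold minimum the WT response counts were 7102 and 9643 at 2 h and 10 h of elf18 and 8477 and 7711 at 2 h and 10 h of Pep2. Those of ein2 were 7298 and 9312 with elf18 and 8105 with Pep2, of efr 7226, of pepr1 pepr2 3446 and 7205, and of bak1 7828 and 10312. The ein2 baseline count became 2176. Interactions became 970 (ein2 at 2 h of Pep2), 1724 (ein2 at 10 h of elf18), 7897 (efr), 7083 and 3619 (pepr1 pepr2 at 2 h and 10 h) and 5383 (bak1 at 10 h). Differences between peptides became 3558 and 7217, and the overlaps 5790 and 5731 in WT and 4878 in the receptor mutants.

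The efr baseline count of 12 became 6 with the filter at log2 7, 0 with only the groups compared, 25 with the replicate number as a block and 48 with array weights. The pepr1 pepr2 count became 2 and the bak1 count 0 with only the groups compared, where AT4G26460 in efr (-2.62) and AT5G66985 in pepr1 pepr2 and bak1 (2.06 and 2.25) were not called. The bak1 count became 29 with array weights. With only the groups compared the ein2 interaction at 2 h of elf18 became 127, and with array weights the bak1 interaction at 2 h became 185.

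Leaving out 1 array gave 1 to 57 for the efr baseline: 7, 1 and 57 without WT untreated replicates 1, 2 and 3, and 7 and 6 without efr untreated replicates 1 and 2. The pepr1 pepr2 baseline ranged from 11 to 19, with 19 without WT untreated replicate 1. The bak1 interaction at 2 h ranged from 45 to 122: 61 and 61 without WT untreated replicates 1 and 2, 55 and 45 without WT Pep2 2h replicates 1 and 2, and 56 without bak1 Pep2 2h replicate 2. The ein2 interaction at 2 h of Pep2 ranged from 204 to 506, with 204 without ein2 untreated replicate 1. The cause was not tested.

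With the replicate number as a block the 2 contrasts in which the numbers pair the arrays gave 3008 for the ein2 response at 2 h of Pep2 and 674 for the ein2 baseline. No call printed for them changed. Elsewhere the samples share only a number, and 40 of the 51 arrays correlated best with arrays of their own number, a hint from the data and not the design. There, besides the efr baseline, the block moved no count of calls given in the report over 1.5 times and changed no call of a named gene. Of the list tests printed in the report it changed 1, the receptor kinase cluster on chromosome 1 in WT at 2 h of elf18, with an adjusted p of 0.038 with an estimated correlation.

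Slopes on the WT response were also taken over probe sets that rose and that fell in WT apart: 0.165 and 0.48 for efr, -0.02 and 0.188 for pepr1 pepr2 at 2 h, 0.513 and 0.798 at 10 h, 1.012 and 0.903 for bak1 at 2 h, 1.178 and 1.067 at 10 h, and 1.027 and 0.928 for ein2 at 2 h and 0.931 and 0.837 at 10 h of elf18. Over probe sets that fell, ein2 at 2 h of Pep2 had 0.887. The bak1 slope at 10 h was 1.116 with no filter, 1.111 with quantile normalization and 1.099 with probe sets chosen on other replicates. It was 1.321 over probe sets whose response differed between pepr1 pepr2 and WT. With 1 array left out it ranged from 1.106 to 1.133, that of pepr1 pepr2 at 2 h from 0.026 to 0.074, and that of ein2 at 2 h of elf18 from 0.971 to 1.013. Of 754 gene list tests, 23 passed with an estimated correlation and 374 with fry, a test whose result depends slightly on the order of the groups in the design.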

Other observations

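All tests of the ein2 array below, with their limits and the search over 16 groups, were chosen only after its values were seen, and the counts of splits further below were set beforehand.

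Replicate 1 of ein2 at 10 h of elf18 stood apart from its group. Over 4 probe sets that were under log2 4 in the other 11 ein2 arrays and over 6 in all 39 arrays of the other lines, its median was 8.26. Another 8 probe sets were over 6 in WT, ein2 and bak1 at 2 h of Pep2 and under 4 in the other 35 arrays without perceived Pep2. Over these 8 its median was 5.08, and their levels at 10 h of Pep2 in WT and bak1 were not limited. A wholly mislabelled array is argued against, since the first set stood at a median of 19.6% of its level in the other lines, and non-mutant seedlings given elf18 are argued against, since adding the WT 10 h group removed 15.3% of the squared difference from the group. RNA of a Pep2-treated sample of another line may be mixed in: adding 20% of bak1 at 2 h of Pep2 removed 65.4%, and 22% of WT at 2 h of Pep2 removed 62.9%, so these sources are not told apart, and the highest value in the other 50 arrays was 41.3%. This is a hypothesis found and tested on the same array, and no biological explanation was tested.

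The 18 comparisons of 3 arrays with 3 have 10 splits each, too few for a share under 0.05. In 17 of them 1 of the 10 splits, the real one, gave as many probe sets. The real counts and the highest other, in that order, were 2112 and 1 at 2 h and 3921 and 0 at 10 h of elf18 in WT, and 3067 and 1 at 2 h and 2537 and 1 at 10 h of Pep2. In ein2 they were 2323 and 2, 3696 and 46, and 3007 and 2 for elf18 at 2 h and 10 h and Pep2 at 2 h. In efr they were 2215 and 4, in pepr1 pepr2 514 and 1 at 2 h and 2154 and 5 at 10 h, and in bak1 2904 and 1 at 2 h and 4663 and 0 at 10 h. For the baselines they were 660 and 11 in ein2, 12 and 2 in pepr1 pepr2 and 10 and 0 in bak1, and for the difference between peptides 1152 and 13 at 2 h and 2194 and 1 at 10 h. For the efr baseline 2 of the 10 splits gave as many, with 12 in the real split and 13 in the highest other.

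Tests of explanations for lower values of the low-oxygen list were run and are not weighed here, because the ein2 array took the place of that pattern. Of its 20 measured members, 14 of them named for their changes here, between 10 and 17 fell in each of the 12 responses. The medians of the 6 others lay between -1.56 (ein2 at 2 h of Pep2) and 0.51 (bak1 at 10 h of Pep2).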
